A study of Mus musculus with 4 samples.

How the data were processed

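RNA-seq and MethylC-seq, a form of bisulfite sequencing that reads the methylation of single cytosines, were made from the prefrontal cortex of female mice at 14 weeks of age. Per the labels, the mice were F1 animals of C57BL6J and Spretus parents with a mutation of Xist on the maternal allele. The order of the strain label was read as mother then father, so C57 is taken as the maternal and Spretus as the paternal allele, and this was checked with Xist and with imprinted genes. There were 2 libraries per assay. Per the labels' protocols, RNA and DNA came from frontal tissue pooled over individuals of separate litters. Nothing in the labels says that the libraries of an assay came from different animals, so p-values measure only the spread between these libraries, which may be technical.

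Per the labels' protocols, ribosomal RNA was depleted and the RNA libraries were made with a kit that marks strand. The submitters' processing notes list TopHat2 2.0.9, Cufflinks 2.1.1, HTSeq 0.6.0, bedtools 2.2.4 and the build mm10, with no role for each. How a read was assigned to an allele, which gene annotation was used and whether counting used strand are not given in the sources used here, so overlapping and antisense genes are treated as uncertain. Per the file headers, the authors deposited for each RNA library raw counts of reads assigned to the C57 and to the Spretus allele per gene, and 1 FPKM value per gene for both alleles together. The tables held 46320 gene identifiers, of which 45815 were found in a table of gene names. Of these, 49 identifiers stood at more than 1 locus with the same counts at each and were used once. All 37 mitochondrial genes were listed at 0. Gene starts counted from 0, since adding 1 matched the RefSeq start for 38.6% of 32303 genes against 2.31% as listed. Gene coordinates are given counted from 1.

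For MethylC-seq the authors deposited a list of regions that differ between the alleles, with the methylation level of each allele as a fraction from 0 to 1. The name of the list points to methylpy as the caller. Its version and thresholds, the cytosine context, the coverage, the number of cytosines per region and whether libraries were pooled are not given in the sources used here. The list held 1613 regions, and 13 regions without levels were left out. A region outside the list was not called, and its level is not known. Region coordinates are given as in the list, in mm10.

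Allelic imbalance was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood functions glmQLFit and glmQLFTest. Each library gave a C57 and a Spretus column, scaled by TMM, with allele as the only term. Genes with at least 10 allele-assigned reads in each library were tested, and p-values were adjusted with the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The residual degrees of freedom were 2, the prior degrees of freedom 9.34 and the common biological coefficient of variation 0.136. Log2 ratios are Spretus over C57, so negative values mean more reads from C57. On simulated counts for 11981 genes this test recovered 59.0% of genes changed 2-fold and 96.0% of genes changed 4-fold, and 4.91% of its calls were false. DESeq2 1.42.0 on the same simulated counts recovered 23.0% and 82.0%, with 0 false calls. These simulated columns were independent, unlike the paired columns of the data. With a simulated library effect shared by the alleles, edgeR recovered 26.0% and 90.0% with 0 false calls, edgeR with the library as a block 80.0% and 98.0% with 2.73% of its calls false, and DESeq2 22.0% and 85.0% with 0 false calls. List tests were camera, with preset and with estimated correlation between genes, and fry, both from limma 3.58.1.

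The alleles of a library come from the same RNA, so the library number pairs the columns by design. Over 7565 autosomal genes with at least 200 reads, the deviations of the C57 and Spretus columns from their means had a correlation of 0.603. The fit with the library as a block was an alternative, and its values stand beside a result where they change it.

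For X-linked genes, the share of reads from the Spretus allele was taken where a gene had at least 20 allele-assigned reads in each library, with exact Clopper-Pearson 95% intervals. A gene was counted as having Spretus reads when the lower limit was above 2% in each library. On simulated counts for 316 genes this rule passed 0% of genes with a true share of 1%, 22.2% of those at 5% and 75.6% of those at 10%. For a share of 0, the limit given is 3 reads of the total. Reads carry no molecular identifiers, so intervals and limits cover counting error only. Shares of X-linked and autosomal genes were compared with a two-sided permutation test of the difference of medians with 100000 resamples and seed 1.

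Counts of regions were compared with two-sided exact binomial tests and Fisher's exact tests. Gene strand and chromosome lengths were not used here. A region was therefore assigned to an X-linked gene when it touched the 2 kb on either side of either end of the gene, in place of the start site alone. It was assigned to an autosomal gene when it touched the gene or the 2 kb on either side. The end of the last listed gene of each chromosome stood in for chromosome length. Correlations between libraries were taken on log2 values with a pseudocount of 0.5. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used for the rest.

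The tests, the gene lists and most alternatives were fixed before the data were examined. The lists were X-linked genes known from mouse work to be expressed from the inactive X chromosome (escape genes), genes of the X-inactivation centre and of noncoding loci of the inactive X chromosome, X-linked genes with roles in brain or general metabolism, maternally and paternally expressed imprinted genes, genes of DNA methylation and repressive chromatin, and markers of 13 cell types or brain regions. Named genes were chosen by rule: list members with enough reads, X-linked genes that passed the rule above, and the 8 called autosomal genes with the highest ratio toward each allele among those with at least 100 reads in each library. Named regions were the 5 with the largest difference each way and those touching or within 2 kb of a listed gene. The genes with the 10 highest mean FPKM values were also named. Results of some genes chosen by these rules are not reported here, while counts and tests include them. Alternatives were other scalings, DESeq2, other read minimums, the library block, exact binomial tests, single libraries, other windows, and other minimums of region length and level difference.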

Results

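RNA-seq and MethylC-seq were carried out on the prefrontal cortex of female F1 mice of C57BL6J and Spretus parents at 14 weeks of age, with 2 libraries per assay. The mice carried a mutation on the maternal allele of Xist, the noncoding RNA that silences the X chromosome it is made from. Separating reads by parental sequence therefore sets an active X chromosome against a silenced one in the same tissue, and asks how expression and DNA methylation differ between the parental alleles. RNA library 1 held 4768237 reads assigned to an allele and RNA library 2 held 1291903, a 3.69-fold difference in depth. The depth behind the methylation levels is unknown. Between the RNA libraries, total reads per gene differed by more than sampling noise, with a chi-square 3.83 times its 16010 degrees of freedom. The Spretus share per gene did not, with a chi-square 0.840 times its 11725 degrees of freedom. Across 11981 genes, which are not independent replicates, log2 counts of the libraries had a Pearson correlation of 0.970 and a Spearman correlation of 0.971.

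The tissue carried the markers of cortical neurons and glia. The pan-neuronal genes Rbfox3, Snap25, Syt1 and Map2 had a median FPKM of 455 in library 1 and 107 in library 2, and the astrocyte list had medians of 29.5 and 4.64. Of the 13 marker lists, 10 had a median mean FPKM of at least 1. Those below it were the choroid plexus, cerebellum and olfactory bulb lists, with medians of 0.383, 1.53 and 1.27 in library 1 and 0.161, 0.381 and 0.0917 in library 2. Among 21 genes of DNA methylation and repressive chromatin, 18 had an FPKM of at least 1 in library 1, with a list median of 10.0. The de novo methyltransferase gene Dnmt3a stood at 19.7 and 5.05 FPKM. Dnmt3b stood at 0.0466 and 0.0504. The highest mean FPKM values were those of Yam1, the ribosomal RNA related Rn18s-rs5, Lars2, the small nuclear RNA gene Rn7sk (49388 and 12087), Gm29216, Gm22988, Gm22513, Gm25939 and Gm10925. Yam1 stands under separate identifiers that overlap each other and Rn18s-rs5 on chromosome 17, so their values cannot be assigned to each alone. FPKM values were a median of 5.80 times higher in library 1. With this factor removed, the oligodendrocyte list median of library 2 was 0.572 times that of library 1, the blood list 0.348 times and the excitatory neuron list 1.47 times.

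Transcription from the X chromosome came almost entirely from the C57 allele, while autosomal genes drew on both alleles. Of 134454 X-linked reads, 4632 (3.45%) came from Spretus, with 3.38% in library 1 and 3.65% in library 2. Xist alone supplied 2953 of these Spretus reads, and the 296 measured genes outside the escape and X-inactivation lists had a pooled share of 0.559%. Autosomal reads were 47.9% Spretus in library 1 and 48.0% in library 2, and single autosomes ranged from 45.8% on chromosome 12 to 49.2% on chromosome 7. The median gene had 0% Spretus reads among 316 X-linked genes (interquartile range 0 to 0.458%) and 48.1% among 9737 autosomal genes (44.7 to 51.0%). No Spretus read was found for 159 of the X-linked genes, where a count of 0 allows a share of up to 0.291% to 4.00% depending on depth. The difference of medians had a permutation p of 1e-05 across genes, the smallest that 100000 resamples can give. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 394 of 397 X-linked genes were called toward C57, and Xist alone toward Spretus. With the library block in the same test with Benjamini-Hochberg adjustment, Gm14735, named after its values were seen, was also called toward Spretus (log2 ratio 1.06, adjusted p = 0.0195), with 34 Spretus and 19 C57 reads in library 1 and 12 and 5 in library 2.

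Xist itself, the mutated gene, came from the Spretus allele in each library. At X 103460375 to 103483217 (ENSMUSG00000086503.3), 2158 of its reads in library 1 were Spretus and 31 were C57, and library 2 gave 795 and 9. Its Spretus share was 98.7% ± 0.210 (SD, n = 2). Apart from Xist, 11 X-linked genes had Spretus reads above the lower limit of 2% in each library. The escape genes among them were Eif2s3x, which encodes a translation initiation factor subunit, at 40.5% ± 1.97 (SD, n = 2), the RNA helicase gene Ddx3x at 30.9% ± 2.05, the histone demethylase genes Kdm5c at 26.6% ± 0.0933 and Kdm6a at 23.4% ± 0.983, the noncoding 5530601H04Rik at 22.0% ± 0.973 and Ftx, a noncoding gene of the X-inactivation centre, at 8.75% ± 0.0309.

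**Figure D1:**
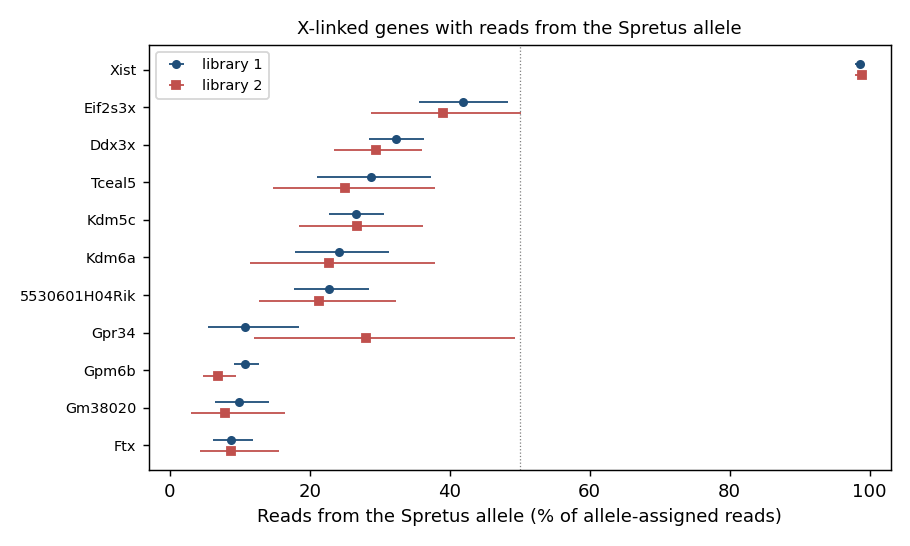
Share of allele-assigned reads from the Spretus allele (%, horizontal axis) for passing X-linked genes of the escape list or outside the escape and X-inactivation lists, with circles for library 1, squares for library 2 and bars for exact 95% intervals of counting error. Xist lies near 98.7% in each library, and the other genes lie below the dotted line at equal shares.

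Passing genes outside the escape and X-inactivation lists were Tceal5, a gene of the transcription elongation factor A-like family, Gpr34, which encodes a receptor known from microglia, Gpm6b, a membrane glycoprotein gene, and Gm38020. Tceal5 (X 136200948 to 136203876) had 37 Spretus and 92 C57 reads in library 1 and 15 and 45 in library 2, a share of 26.8% ± 2.60 (SD, n = 2). Gpm6b (X 166238911 to 166388988) stood at 10.8% and 6.85%, with exact 95% intervals of 9.10 to 12.7% and 4.79 to 9.45%. Gpr34 had 11 Spretus and 91 C57 reads in library 1 and 7 and 18 in library 2, and its locus lies inside that of Cask. Gm38020 stood at 8.87% ± 1.38 (SD, n = 2) and lies inside Ftx, so its reads cannot be assigned to it alone. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Ddx3x had a log2 ratio of -1.07 (SE 0.24, adjusted p = 0.0143), Tceal5 -1.36 (SE 0.37, adjusted p = 0.0451) and Eif2s3x -0.43 (SE 0.25, adjusted p = 0.419). Eif2s3x was thus the only passing gene other than Xist without a call toward C57. Library 1 alone, the deeper library, passed 21 genes, and a lower limit above 10% passed 7.

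Escape from silencing was not seen for every listed gene at this depth. Of 16 measured genes of the escape list, 7 passed, Xist among them, and 6 had a Spretus share under 1%. Xist is made from the X chromosome it silences, so its share is no measure of escape. Pbdc1 had 32 Spretus and 97 C57 reads in library 1 and 2 and 26 in library 2. Tmem29 had 27 and 169 in library 1 and 2 and 42 in library 2. Neither passed in library 2. Usp9x stood at 0.368% and Shroom2 at 0.221% of summed reads. Syap1 had none in 181 reads, which allows a share of up to 1.66%, and Bgn none in 95, which allows up to 3.16%. Of the 6 measured genes of the X-inactivation centre and noncoding loci, Xist and Ftx were among those that passed, and Firre stood at 1.65% (exact 95% interval 0.947 to 2.67%, with 1.86% in library 1 and 0.614% in library 2). The 39 measured X-linked genes with roles in brain or metabolism had a median share of 0.217%, and Tceal5 and Gpm6b alone passed. Atrx had 3 Spretus reads in 1666, and Gria3 none in 767, which allows up to 0.391%. Above 2% in summed reads but not passing were, among others, Maoa at 7.24% (8.24% in library 1 and 3.92% in library 2) and Tspan7 at 2.41% (3.27% and 0.546%). As sets, the escape and brain lists lay toward C57 in camera with a preset correlation (adjusted p of 1.83e-15 and 5.79e-56). Camera compares a list with all other tested genes, most of them autosomal, and 394 of 397 X-linked genes were called toward C57. Nearly any X-linked list would therefore lie toward C57, so these list tests say nothing particular to escape or brain genes. With an estimated correlation (0.146 and 0.318) both lists had adjusted p = 0.0435. With the library block, camera gave adjusted p of 5.12e-12 and 2.3e-37 with the preset and 0.229 for each with the estimated correlation. Fry with the block gave adjusted p = 0.164 for each. The estimated correlation and fry rest on the residual degrees of freedom, 2 without the block and fewer with it, so they decide nothing here.

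Most called imprinted genes favoured the allele of the parent their list names. Of 24 tested genes of the paternal list, 20 were called toward Spretus, among them Snrpn and Snhg14 of the Prader-Willi region, Peg3, Kcnq1ot1, Mest, Nap1l5 and Ndn. Of 16 tested genes known for maternal expression, 9 were called toward C57, namely Meg3, Rian, Mirg, Ube3a, Kcnk9, Copg2, Trappc9, Ago2 and Commd1, and 0 toward Spretus. The Spretus share was 99.7% ± 0.447 (SD, n = 2) for Snrpn, 98.4% ± 0.354 for Kcnq1ot1, 93.7% ± 1.23 for Peg3, 2.13% ± 0.144 for Meg3 and 12.8% ± 1.19 for Ube3a. H13 (33.5% ± 1.30) and Igf2 (25.2% ± 1.42) were called toward C57 although they stand in the paternal list. That list names genes and not single transcripts, so a place in it does not settle which parent's allele each transcript comes from. Adam23, Sfmbt2 and 7 genes of the maternal list were not called, Igf2r at 45.2% ± 3.96 and Cd81 at 49.1% ± 0.199 among them. With the library block, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called Adam23 toward Spretus (log2 ratio 0.253, adjusted p = 2.60e-04).

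**Figure D2:**
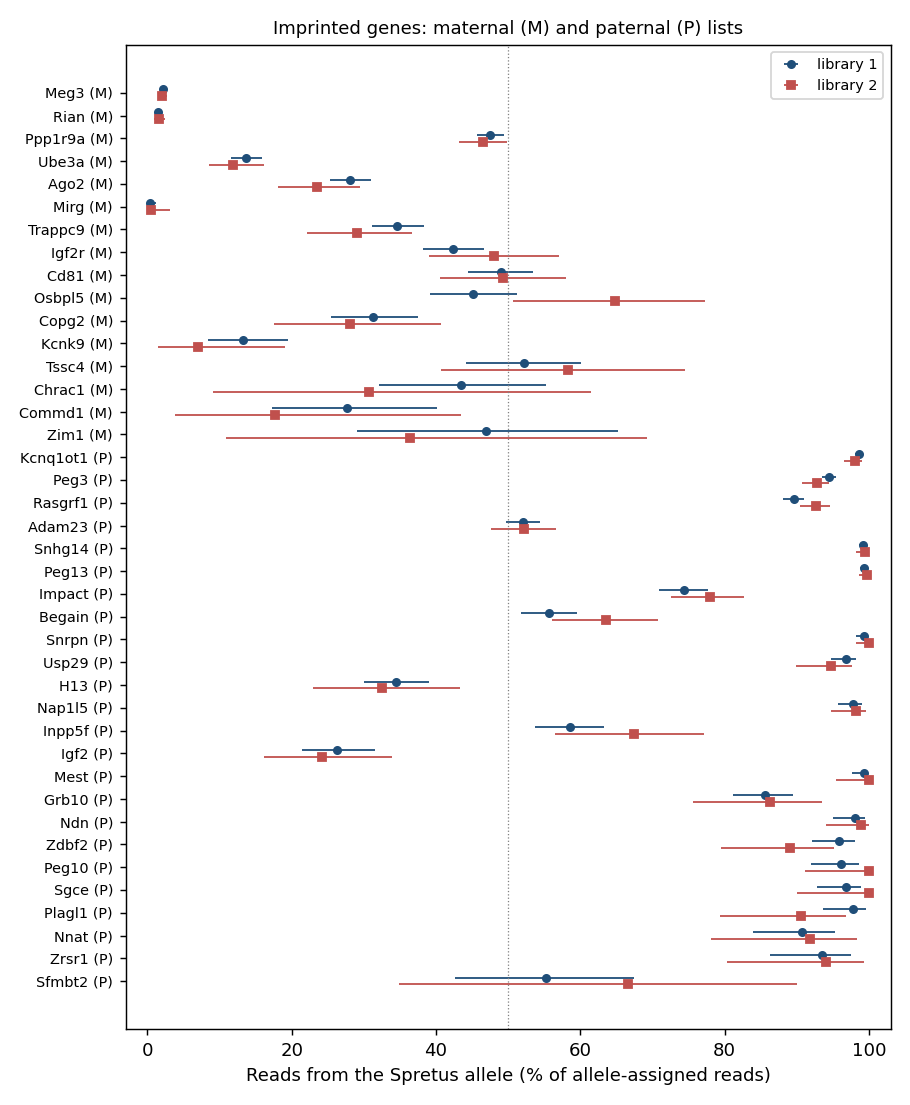
Share of allele-assigned reads from the Spretus allele (%) for the tested genes of the maternal and paternal imprinted lists, with a mark per library and exact 95% intervals of counting error. Genes of the paternal list reach from 25.2% for Igf2 to 99.7% for Snrpn, and genes of the maternal list from 0.489% for Mirg to 55.3% for Tssc4, as means of the libraries.

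These calls came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Adjusted over the list alone, the counts were the same, at 9 and 0 for the maternal list and 20 and 2 for the paternal list. Meg3 had a log2 ratio of -5.46 (SE 0.48, adjusted p = 6.58e-06) and Snrpn of 8.03 (SE 0.48, adjusted p = 2.68e-07) in this test with Benjamini-Hochberg adjustment. Of 40 tested list members 31 were called, against 598 of 11544 other autosomal genes (Fisher's exact test, two-sided, p = 5.07e-32). That test treats genes of the same cluster, such as Meg3 and Rian, as independent. The library block called 9 maternal list genes toward C57, and 21 and 2 paternal list genes toward Spretus and C57. It called 22.5% of autosomal genes, against 5.43% in the planned fit, so the contrast is smaller with the block, where it was not tested. In camera with a preset correlation the maternal list lay toward C57 (adjusted p = 1.11e-06) and the paternal list toward Spretus (adjusted p = 7.59e-22). With an estimated correlation each list had adjusted p = 0.0435. With the library block, camera with a preset correlation kept both (adjusted p = 1.25e-05 and 5.08e-16). With the block, camera with an estimated correlation (adjusted p = 0.229 for each) and fry (adjusted p = 0.164 for each) gave no call. These 2 tests rest on the residual degrees of freedom, 2 without the block and fewer with it. Their outcomes, with or without the block, therefore decide nothing about the lists. Copg2, Commd1, Begain, H13 and Inpp5f were not called by DESeq2.

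Away from the X chromosome, the planned fit, with allele as its only term, called 629 of 11584 autosomal genes imbalanced, 352 toward C57 and 277 toward Spretus. The fit with the library as a block, which follows the pairing of the alleles, called 2603, so the number of imbalanced genes depends on the fit. Imprinted clusters supplied most of the genes with the highest ratios. Toward C57, Gm37899, Mirg, Rian and Meg3 lie within 109541001 to 109749460 on chromosome 12, and Gm37899 had 1 Spretus read in library 1 and 0 in library 2. Ube3a followed, along with Clcn4-2, 4933431E20Rik and Nvl, which are not in the imprinted lists. Clcn4-2, a chloride transporter gene at 7282316 to 7299511 on chromosome 7, had 67 Spretus and 800 C57 reads in library 1 (7.73%, exact 95% interval 6.04 to 9.71%) and 4 and 266 in library 2 (1.48%, 0.405 to 3.75%). 4933431E20Rik had a share of 14.6% ± 0.293 (SD, n = 2), and Nvl, an ATPase gene of ribosome assembly, 23.1% ± 0.498.

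Toward Spretus, the highest ratios were those of Gm38393, Snrpn and Snhg14 on chromosome 7, Peg13 on chromosome 15, Kcnq1ot1, Nap1l5, Usp29 and Peg3. Gm38393 (59974149 to 60005064) overlaps Snrpn, so its 99.6% ± 0.126 (SD, n = 2) cannot be assigned to it alone. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, log2 ratios were -4.00 for Clcn4-2 (SE 0.34, adjusted p = 5.71e-06), -1.60 for Nvl (SE 0.18, adjusted p = 6.44e-05) and 7.85 for Peg13 (SE 0.39, adjusted p = 9.53e-08). With the library as a block, 2603 autosomal genes were called, the 629 among them, and DESeq2 called 255. The split of the calls, 56.0% toward C57, became 69.7% (385 of 552) when the alleles of a library shared its total, which shifted the median autosomal log2 ratio from 0.02 to -0.11. Since the cross was made in 1 direction, strain and parent of origin cannot be told apart for genes outside the lists.

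Listed regions of methylation difference were mostly higher on Spretus on the X chromosome and mostly higher on C57 on autosomes. Of 594 X-linked regions, 519 (87.4%, exact 95% interval 84.4 to 89.9%) were more methylated on the silenced Spretus allele. Of 1006 autosomal regions, 268 (26.6%, 23.9 to 29.5%) were. The X chromosome held 37.1% of the regions on 6.49% of the span of listed genes, or 3.48 regions per Mb against 0.310 to 0.521 on the autosomes. Its Spretus-higher regions had a median level of 0.0150 on C57 and 0.706 on Spretus and a median length of 466 bp. The 738 autosomal C57-higher regions had a median level of 0.944 on C57 and 0.0365 on Spretus and a median length of 30.5 bp.

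**Figure D3:**
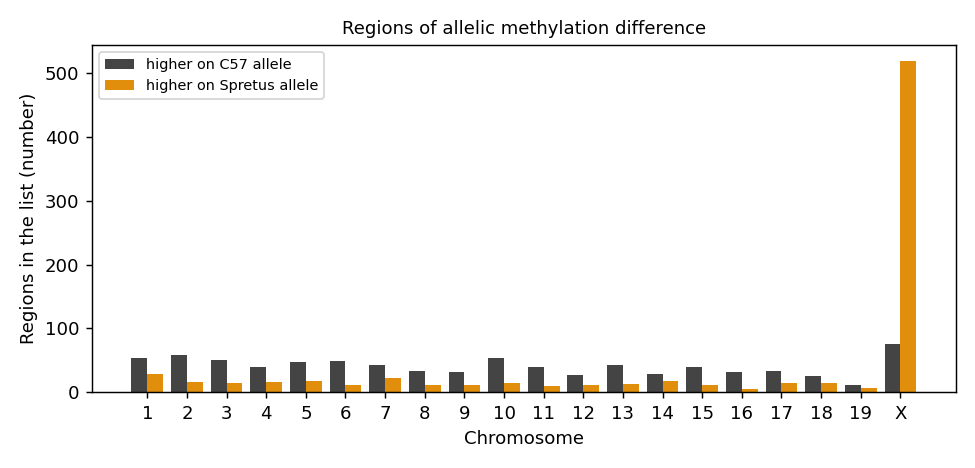
Listed regions by chromosome and direction, as the number of regions more methylated on each allele. The X chromosome stands apart with 519 regions higher on Spretus and 75 higher on C57.

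The share of Spretus-higher regions differed from equal numbers on the X chromosome (exact binomial test, two-sided, p = 1.19e-82) and on autosomes (p = 2.30e-51). The chromosome classes differed from each other by Fisher's exact test (odds ratio 19.1, p = 2.98e-132). The autosomal share changed with region length. Of 445 autosomal regions under 50 bp, 409 were higher on C57, against 211 of 361 regions of at least 200 bp, where 41.6% were higher on Spretus (exact binomial p = 0.00155). The bases under the regions were not analysed. The autosomal direction may therefore reflect in part cytosines of the C57 reference that are another base in Spretus, mainly in short regions.

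**Figure D4:**
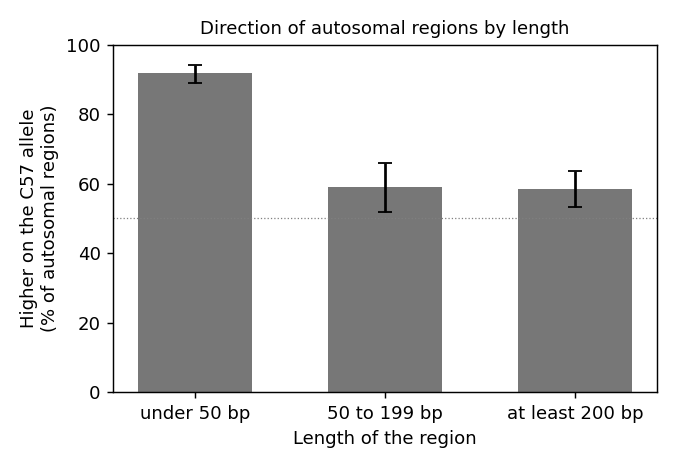
Percent of autosomal regions that were more methylated on the C57 allele (vertical axis) in classes of region length, with exact 95% intervals of counting error and a dotted line at equal numbers. The share is 91.9% under 50 bp, 59.0% from 50 bp to under 200 bp and 58.4% at 200 bp or more.

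Some regions of strong difference lay at known imprinted loci, most of these higher on the maternal C57 allele. Most autosomal regions lay elsewhere, and enrichment at imprinted loci was not tested. Within 2 kb of imprinted list genes lay 38 of the 1006 autosomal regions, 30 higher on C57 and 8 higher on Spretus. Of these, 30 were at least 200 bp long with a level difference of at least 0.5, at 29 listed genes. The longest, at 72806561 to 72811582 on chromosome 15, covers Peg13 inside Trappc9, with levels of 0.960 on C57 and 0.0683 on Spretus. Regions higher on C57 also covered parts of Mest (chromosome 6, 30736807 to 30739830, 0.917 and 0.00765), Kcnq1ot1 inside Kcnq1 (chromosome 7, 143294269 to 143296758, 0.936 and 0.0191), Snrpn (chromosome 7, 60003279 to 60005283, 0.912 and 0.0164) and Airn and Igf2r (chromosome 17, 12741096 to 12742949, 0.916 and 0.0523). Regions higher on Spretus, the paternal allele, lay beside H19 (chromosome 7, 142579875 to 142582519, 0.0535 and 0.886), at Meg3 (chromosome 12, 109539967 to 109541807, 0.00693 and 0.872), in Zdbf2 and in Cdkn1c.

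On the X chromosome, 32 regions lay near escape or X-inactivation list genes, 14 higher on C57 and 18 higher on Spretus. Xist had 3 regions, each higher on C57, with levels of 0.982 and 0.0120 at 103480917 to 103481385, 0.918 and 0 at 103482146 to 103482233 and 0.876 and 0 at 103483232 to 103484046. Firre, a noncoding gene, had 9 higher on C57 and 1 higher on Spretus. Rlim, a ubiquitin ligase gene beside the X-inactivation centre, had a 1415 bp region at 103980509 to 103981924 with levels of 0.00936 and 0.641. The largest differences by value were in short regions. Those higher on C57, with levels of 1 and 0, included a 20 bp region in Rhcg (chromosome 7, 79610143 to 79610163) and an 18 bp region in Opcml (chromosome 9, 28276684 to 28276702). Those higher on Spretus included a 13 bp region in Fhod3 (chromosome 18, 24940243 to 24940256, 0 and 0.982) and an 8 bp region in Fah (chromosome 7, 84594667 to 84594675, 0 and 0.967).

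X-linked genes with Spretus reads carried a region near either end less often in number than other measured genes, with no call in the planned test. Such a region lay within 2 kb of an end of 4 of 12 passing genes, Xist, Gpm6b and Tceal5 among them, and of 186 of 304 other measured genes (61.2%), with an odds ratio of 0.317 (Fisher's exact test, two-sided, p = 0.0711). Xist owed its place to regions higher on C57. Counting Spretus-higher regions alone, a choice made after the data were seen, gave 3 of 12 against 186 of 304 (odds ratio 0.211, Fisher's exact test, p = 0.0160), but 5 kb windows gave no call (odds ratio 0.399, p = 0.133). Eif2s3x, Ddx3x, Kdm5c, Kdm6a and Ftx had none within 2 kb of an end. Further inside the gene, and taken in by the 5 kb windows, Ddx3x had Spretus-higher regions of 570 and 34 bp and Kdm6a 1 of 757 bp.

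On autosomes, genes with a region were called imbalanced more often, and the less methylated allele was mostly the higher one. Of 365 tested genes with a region in or within 2 kb of the gene, 43 (11.8%) were called, against 586 of 11219 without (5.22%), an odds ratio of 2.42 (Fisher's exact test, two-sided, p = 1.51e-06). In 33 of the 43 (76.7%, exact 95% interval 61.4 to 88.2%) the less methylated allele had more reads (exact binomial test, p = 6.06e-04). Peg13, Snrpn, Mest and Kcnq1ot1, each with more Spretus reads and a region higher on C57, show this pattern, and Meg3 shows it the other way round. Without members of the imprinted lists, an alternative added after the data were seen, the odds ratio was 1.26 (22 of 343 genes, Fisher's exact test, p = 0.320) and the less methylated allele was higher in 17 of 22 (exact binomial test, p = 0.0169). This does not remove every gene at an imprinted locus, since Gm38393, outside the lists, overlaps Snrpn and shares its region. All these tests also treat genes that share a region, such as Peg10 and Sgce, as independent. With DESeq2 calls the odds ratio was 4.38, and with regions of at least 200 bp alone, also chosen after the data were seen, it was 5.36. With the library block, the odds ratio was 1.39 (Fisher's exact test, p = 0.00610) and 66 of 102 genes had the less methylated allele higher.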

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

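A few genes outside the allele comparisons took very different shares of the FPKM values of the RNA libraries. Yam1, Rn18s-rs5 and Lars2 together held 27.4% of the summed FPKM of library 1 and 86.3% of that of library 2, although ribosomal RNA was depleted per the labels' protocols. No biological explanation was tested, since both libraries belong to the same group.

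Genes listed on the Y chromosome had a summed FPKM of 15.0 in library 1 and 3.20 in library 2 in tissue labelled female, and none had an allele-assigned read. Gm37158 stood at 8.58 and 2.22 FPKM, and Erdr1, which is known from the pseudoautosomal region shared with the X chromosome, at 5.78 and 0.864. Uty stood at 0.605 and 0.118 and Kdm5d at 0.0328 and 0.00358.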

How the results depend on the processing

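Alternatives that count Spretus-higher regions alone at X-linked genes, leave out regions under 200 bp or imprinted genes, use library-block calls for regions, rescale FPKM or apply the binomial test to single libraries were chosen after the data were seen. The count of imbalanced autosomal genes (629) was 255 with DESeq2, 2603 with the library as a block (the pairing by design), 2545 with an exact binomial test on summed reads, which covers counting error only, 1290 with no read minimum, which tests more genes, and 165 with at least 50 reads, which tests fewer. In 1 library the binomial test called 372 to 1829 genes, fewer in the shallower library 2. The rule of a 2-fold size gave 479 genes in both libraries and 710 to 1276 in single libraries, more in library 2. The X-linked rule gave 12 genes, 12 to 21 with a replicate left out, 21 being library 1 alone, and 7 with a lower limit above 0.10. The camera tests of the imprinted, escape and brain lists lost their call with the library block and an estimated correlation (adjusted p = 0.229 for each). They kept it with the block and a preset correlation. The estimated form rests on the residual degrees of freedom, 2 without the block and fewer with it, so this loss decides nothing about the lists. The block also called Adam23 and the X-linked Gm14735 toward Spretus, and changed no other call of a named gene. At X-linked genes, the odds ratio of 0.317 was not called, while counting Spretus-higher regions alone gave 0.211, 0.259 with 1 kb windows, 0.214 with most of the region inside and 0.0912 with a lower limit above 0.05, each called. With 5 kb windows Spretus-higher regions gave 0.399, which was not called (Fisher's exact test, p = 0.133). The same settings with regions of either direction gave no call. On autosomes the odds ratio of 2.42 ranged up to 5.36 and fell to 1.26 without imprinted list genes and was no longer called, since list members had supplied called genes with regions. The cause of the other changes was not tested. The difference in Spretus share between autosomes and the X chromosome (48.0 to 48.1 points as medians over genes, 44.4 as shares of all reads) and the directions of X-linked (87.4 to 89.9% higher on Spretus) and autosomal regions (24.9 to 41.8%) kept their direction and their side of the threshold under the alternatives run on them. Called genes of the maternal list numbered 7 to 10, those of the paternal list 14 to 21, and marker lists with a median of at least 1 numbered 8 to 12. Of named genes, 5 lost their call with DESeq2, 3 with at least 50 reads, 2 with a common library size and 1 with autosomal totals. Cd81, not called under any alternative, turned from a log2 ratio of 0.0747 to -0.0524 with a common library size, and no other named gene turned. Minimums on the number of cytosines per region were not run, since the number is not given in the sources used here. Library 2, with 1291903 reads, limits the X-linked rule: a true share of 5% passed for 22.2% of simulated genes.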

Other observations

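The tests of region length, of Spretus levels in longer regions, of the median X-linked share and of called genes over 1 Mb from imprinted genes were chosen after the result was seen. Listed regions more methylated on the silenced X chromosome lay near expressed genes more often than near genes with little or no expression. Whether regions could be called equally well near both was not tested. Of 509 X-linked genes with an FPKM of at least 1 in library 1, 270 (53.0%) had a Spretus-higher region within 2 kb of an end, against 53 of 1831 genes (2.89%) with an FPKM under 0.1 (Fisher's exact test, two-sided, odds ratio 37.9, p = 1.14e-152). Regions of the opposite direction were more frequent inside Firre and Xist, though most lay elsewhere. Of 75 X-linked regions higher on C57, 11 (14.7%) lay inside Xist, Firre, 4933407K13Rik or Ftx, against 2 of 519 higher on Spretus (Fisher's exact test, two-sided, odds ratio 44.4, p = 4.17e-09), a test that treats regions of the same gene as independent. Firre held 9 of the 11, Xist 2 and the other loci 0. Among genes with an FPKM of at least 1, the median X-linked gene stood at 0.969 times the median autosomal gene in library 1 and at 1.04 times in library 2.

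Among called autosomal genes, 62 had a Spretus share under 5% or above 95% in each library, and 12 of these were imprinted list members. Others lie in the same clusters, such as Gm26945 and B830012L14Rik between the start of Rian and Mirg on chromosome 12, each with 0 Spretus reads. Gm26945 lies inside Rian, so its reads cannot be assigned to it alone. Further genes lie elsewhere. All of these are named after their values were seen. The complement receptor gene Cr2 and the thymocyte gene Themis had no C57 read, with 210 and 125 Spretus reads, and Aldh3b3 had 2 C57 and 307 Spretus reads. Ly6c1, of a gene family with similar members, had 149 C57 reads and 0 Spretus reads. Of 53 adjacent, non-overlapping pairs of called genes outside the lists within 100 kb, 38 (71.7%) favoured the same allele. Permuting directions gave 50.9% on average (37.7 to 64.2%, permutation p = 0.00165 with 100000 resamples). Over 1 Mb from any listed gene, 35 of 50 pairs (70.0%) did so (permutation p = 0.00468). Control shared by neighbouring genes is a hypothesis that may account for this, and sequence differences shared by neighbours were not tested.

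Autosomal regions were mostly higher on C57. A cytosine of the C57 reference that is another base in Spretus could read as unmethylated on the Spretus allele, and the share of C57-higher regions was 33.5 percentage points higher under 50 bp than at 200 bp or more, in line with such sequence differences in the short regions. Of the short C57-higher regions, 78.7% had a Spretus level of at most 0.05. Of those of at least 200 bp, 17.5% had (37 of 211), which decides nothing, since in a longer region only some cytosines need differ in sequence. The bases under the regions were not analysed here, and a difference between the strains or the parents, which the design names, stays open as untested.

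Tceal5, Gpr34, Gpm6b and Gm38020 had Spretus reads without being in the escape or X-inactivation lists. Reads assigned to the wrong allele at one rate on the whole X chromosome are argued against by a median Spretus share of 0% over 296 measured genes outside the lists. Reads from an overlapping gene of the escape list concern 1 of the 4, Gm38020 inside Ftx. Expression from the inactive X chromosome in non-neuronal cells as a whole is argued against by 25 other X-linked genes of glia, vessels and immune cells, of 34 listed before the test, whose pooled share was 0.245% (9 of 3677 reads, exact 95% interval 0.112 to 0.464%), with 1 Spretus read in 41 for Tmsb4x at 391 FPKM and 0 in 230 for Sat1 at 27.6 FPKM. Tceal5 and Gpm6b, but not Gpr34 and Gm38020, had Spretus-higher regions within 2 kb of an end. So had 186 of 304 measured genes that did not pass, and what such regions mean for escape was not tested. Reads from similar genes of the same family were not tested, so escape of these 4 genes is a hypothesis only.

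Clcn4-2 stands on chromosome 7 in mm10 and is known to be X-linked in Mus spretus, so a Spretus copy of the gene on the silenced X chromosome may account for its low share. Only 5 of 3588 autosomal genes with at least 100 reads in each library had a share as low, itself included, and 2 of the 5 were outside the imprinted lists. The bound set against this reading, no Spretus-higher region within 2 kb of the gene, was met with 0 regions, yet 60 of 159 measured X-linked genes without a Spretus read (37.7%) had no such region either, so the bound was wrong and decides nothing, a judgement made after the count was seen. The share, but not the region count, had been seen when that test was written. The libraries stood at 7.73% and 1.48%, and an X-linked copy and a strain difference in expression cannot be told apart here, since the cross was made in 1 direction.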
